A study of Arabidopsis thaliana with 9 samples.

How the data were processed

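Whole seedlings of Arabidopsis thaliana were profiled by RNA sequencing in 3 groups of 3 libraries: the wild type Col-0, the AtCXE15-OE line, which overexpresses a carboxylesterase that degrades strigolactones, and atd14-1, a mutant of the strigolactone receptor gene D14. Per the labels' protocols, seedlings were grown at 22 °C under 16 h of light and 8 h of dark with no treatment, and polyadenylated RNA was fragmented, primed with random hexamers and copied with DNA polymerase I, a procedure that does not mark the strand. The labels disagree on age, which is given as 8 days in the sample characteristics and 10 days in the extraction protocol. No label says whether the libraries of a group came from separately grown plants, so p-values measure the spread between these libraries, which may in part be technical. No batch, harvest date or harvest hour was given in the sources used here. A difference in harvest or handling between the groups can therefore not be told apart from genotype.

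The deposited table holds raw counts per gene for the 9 libraries, one column each, not normalized. From 3 to 11, odd numbers are more frequent than the even numbers beside them (2938 values of 3, 1491 of 4, 1987 of 5 and 1095 of 6), while 1 is less frequent than 2 (1947 and 2478 values), for a reason not given in the sources used here, so that values near the floor are uncertain. HISAT2, Picard, SAMtools 0.1.18, DESeq 1.39.0 and the build TAIR10 are named, per the submitters' processing notes. The counting tool, its strand setting and its handling of reads that map to several places are not given in the sources used here. The table has 27814 rows, of which 27366 carry a locus ID and 448 are loci assembled without one. Start and end are those of the annotation in 4700 of the matched rows, and 72 rows span over 100 kb. Where loci overlap, and for near-identical paralogs, a count may therefore have been assigned to either gene. Locus IDs were matched to the RefSeq annotation of the TAIR10.1 assembly, which held 26694 of them and a symbol for 10367. The end coordinates in the table stay within the chromosome lengths of that assembly, and coordinates given below are those of the annotation unless stated.

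Library totals ranged from 37724263 to 54421069 counts. At these depths a count of 3, taken as the floor, corresponds to 0.0551 to 0.0795 CPM, which covers counting error only. Correlations of log2 CPM between libraries of a group were 0.973 to 0.978, and no pair agreed within sampling noise (chi-square per degree of freedom of 25.0 or more), so that all 9 libraries were kept as separate samples.

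Genes were tested with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood test with robust dispersion estimates, TMM normalization and a group-aware filter on low counts that left 21425 genes. All 9 libraries entered 1 fit with group means only, and 3 comparisons were taken from it. Adjusted p-values are Benjamini-Hochberg values over all genes of a comparison with a threshold of 0.05. Levels are TMM-scaled CPM, which is scaled by library total and composition factor, as mean ± SD over 3 libraries. The SE of a log2 fold change was computed as its absolute value divided by the square root of the F statistic, and is approximate. The 2 lines were compared with the same Col-0 libraries, so overlaps and correlations were set beside 40 simulations of unchanged groups.

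A total of 23 gene lists with 364 distinct genes were fixed before the data were examined, as were the comparisons, the tests and the rule for naming genes. A listed gene was kept where the annotation's symbols for its ID held the listed symbol, which left out 8 genes. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move on balance one way, and does not compare them with other genes. Named genes were CXE15, D14 and all measured members of the 2 strigolactone lists, the 6 highest and 6 lowest log2 fold changes per line among called genes with a symbol, a mean of 1 CPM or more and no overlap of replicate values, up to 4 members with the smallest adjusted p from each other list, the 5 highest and 5 lowest for genes shared by the lines and for the direct comparison, and called neighbours of both loci. The annotation pairs AT5G06570 with no CXE15 symbol. The pairing used here comes from the list fixed beforehand.

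The procedure was tested on simulated counts for the same 21425 genes, with 200 genes changed per line in each of 5 draws. For AtCXE15-OE against Col-0 it recovered 42.4% of genes changed 1.5-fold, 78.8% of those changed 2-fold and 94.2% of those changed 4-fold. For atd14-1 against Col-0 it recovered 43.3%, 78.5% and 95.8%. Genes that had not been changed made up 6.88% and 7.42% of the calls, above the nominal 5%. Alternatives covered DESeq2 1.42.0, limma-voom, other size factors, other filters and thresholds, fits to the 6 libraries compared, the replicate number as a block, and each library left out in turn. Summing overlapping loci was added after the data had been seen. Such a sum includes counts of other genes, so a smaller fold change in it need not mean that the gene itself changed less.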

Results

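Polyadenylated RNA from whole seedlings was counted per gene in 9 libraries, 3 each of Col-0, AtCXE15-OE and atd14-1, with totals of 42959683, 39837851 and 43311790 counts in Col-0, 42143351, 54421069 and 50998216 in AtCXE15-OE, and 37724263, 53238488 and 45043865 in atd14-1 (replicates 1 to 3). Strigolactones are plant hormones that restrain shoot branching and are perceived by the receptor D14. The series set a line that overexpresses a strigolactone-degrading carboxylesterase beside a signalling mutant and the wild type, to profile responses that depend on strigolactones. Levels are given as TMM-scaled CPM. On the first principal component (19.7% of the variance) AtCXE15-OE lay between Col-0 and atd14-1, and the second (15.4%) separated AtCXE15-OE from both.

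The overexpressed and the mutated gene were examined first. CXE15 (AT5G06570, chromosome 5, 2007419 to 2011179) was at 3.94 ± 0.193 CPM in Col-0 and 822 ± 123 CPM in AtCXE15-OE (SD, n = 3), a 209-fold difference (log2 fold change 7.70 ± 0.12 SE, edgeR adjusted p = 5.53e-12). In the deposited table this locus extends from 2007600 to 6762804, with a gene length of 1942 bases. Its count may therefore not be limited to the annotated gene, and counts outside that gene were not measured. D14 (AT3G03990, chromosome 3, 1033579 to 1035237) was at 45.0 ± 0.317 CPM in Col-0, 44.5 ± 0.974 CPM in AtCXE15-OE and 6.74 ± 0.226 CPM in atd14-1. It was thus 6.67-fold lower in the mutant (log2 fold change -2.74 ± 0.07, adjusted p = 1.52e-11) and did not pass the edgeR test in AtCXE15-OE (adjusted p = 0.96). In atd14-1, CXE15 was slightly lower (3.04 ± 0.08 CPM, log2 fold change -0.37, edgeR adjusted p = 0.0315), a call that was lost when any 1 of the 6 libraries compared was left out (log2 fold changes of -0.41 to -0.34).

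**Figure D1:**
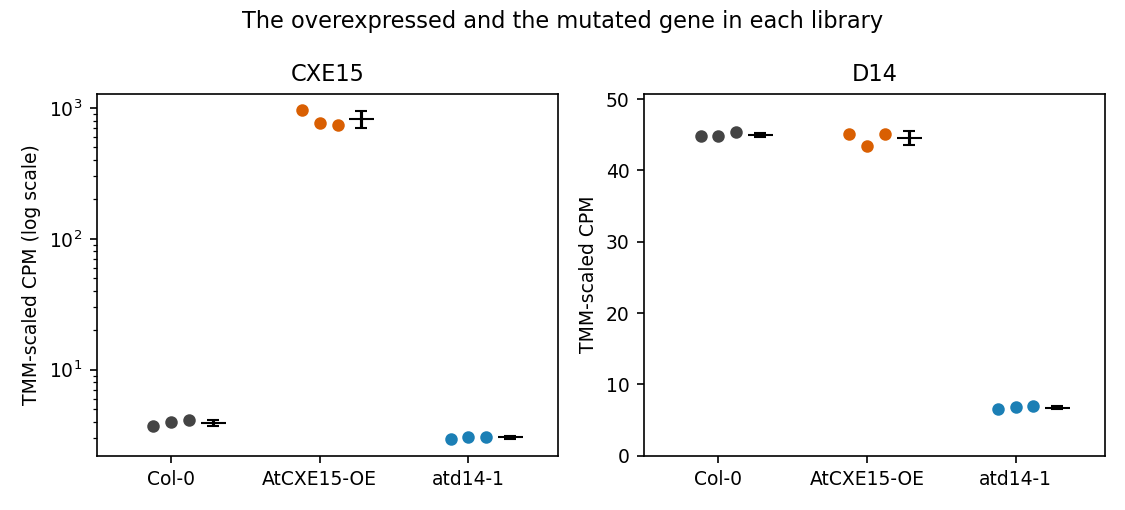
TMM-scaled CPM of CXE15 (log axis) and D14 (linear axis) in each library, with the mean and SD of 3 libraries at the right of each group. CXE15 is near 822 CPM in AtCXE15-OE against 3.94 CPM in Col-0, and D14 is at 6.74 CPM in atd14-1 against 45.0 CPM in Col-0.

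The first comparison asked how seedlings that overexpress CXE15 differ from Col-0. The strigolactone biosynthesis genes CCD7 and CCD8, which encode carotenoid cleavage dioxygenases, rose from 0.173 ± 0.0816 to 1.03 ± 0.323 CPM and from 2.15 ± 0.225 to 7.56 ± 1.1 CPM (log2 fold changes 2.57 ± 0.39 and 1.81 ± 0.14, edgeR adjusted p = 0.00272 and 6.89e-06). CCD7 in Col-0 was close to the floor (0.095, 0.257 and 0.167 CPM), so that the size of its fold change is uncertain. Of the other biosynthesis genes, D27 (-0.41), MAX1 (-0.04) and LBO1 (0.19) did not pass the test. Of the 5 genes of the list 2 rose, and 2 rose and 1 fell adjusted over the list alone, with a camera adjusted p of 0.0386 and an adjusted p = 0.26 with an estimated correlation. The camera call was also lost without Col-0 replicate 3 (adjusted p = 0.182), without AtCXE15-OE replicate 1 (0.122) and with library size as the only scaling (0.061). With overlapping loci summed, an alternative added after the data had been seen, the group that holds CCD8 had a log2 fold change of 0.24 (edgeR adjusted p = 0.0556). That sum holds counts of other loci, so its smaller value does not show that CCD8 itself rose less. Among 14 measured signalling and response genes, SMXL6 and SMXL7, which encode targets of D14-dependent degradation, fell (log2 fold changes -0.29 and -0.24, edgeR adjusted p = 0.0203 and 0.0397). The list's camera adjusted p was 0.209 (0.0458 with a stricter filter), with 2 members falling adjusted over the list alone. By fry, which tests whether members move on balance one way and does not compare them with other genes, the list was lower (adjusted p = 0.0421). Its median log2 fold change was -0.02, with 9 members below 0 and 5 above. Both SMXL calls were lost without any 1 Col-0 library, without AtCXE15-OE replicate 2 or without AtCXE15-OE replicate 3 (adjusted p up to 0.0859 and 0.161 over the alternatives). The SMXL7 call was also lost with library size as the only scaling (adjusted p = 0.084) and with only the 6 libraries compared (0.0617). The branching regulator BRC1 was at 0.138 CPM in Col-0 and 0.204 CPM in AtCXE15-OE, close to the floor, and did not pass the test. MAX2, SMXL2, SMXL8, BRC2, HB21, HB40, HB53, KUF1, BBX20 and NCED3 did not pass it in either line. Of these, HB40 and HB53 were above 0 in both lines under every alternative run on them, and SMXL2, BBX20 and NCED3 below 0. DLK2, left out of the list for lack of a symbol, was at 0.18 in AtCXE15-OE and 0.14 in atd14-1 (edgeR adjusted p = 0.669 and 0.616).

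The clearest group change in AtCXE15-OE was in genes induced by touch and wounding, of which 14 of 16 measured members fell, and 15 when adjusted over the list alone. SZF1, a zinc finger gene, fell from 138 ± 7.36 to 52.9 ± 3.00 CPM (log2 fold change -1.39 ± 0.06, edgeR adjusted p = 1.62e-08). WRKY40, a defence transcription factor, had a log2 fold change of -1.51 ± 0.11 and the xyloglucan endotransglucosylase TCH4 one of -0.85 ± 0.06 (both with edgeR adjusted p = 2.74e-06). With overlapping loci summed WRKY40 was at -0.99. The list fell by camera (adjusted p = 4.08e-36) and with an estimated correlation (adjusted p = 0.0115). It was the only one of the 23 lists to hold with an estimated correlation in this comparison. Of 26 salicylic acid and defence genes 5 fell, and 7 adjusted over the list alone, among them WRKY33 (-0.76 ± 0.06) and WRKY46 (-1.11 ± 0.15), with a camera adjusted p of 5.69e-05 and an adjusted p = 0.318 with an estimated correlation. Without Col-0 replicate 1 the count was 3, and WRKY53, another of the 5, was at 0.014 with overlapping loci summed.

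Nitrate assimilation genes were also lower in AtCXE15-OE, with 4 of 8 measured members falling, over all genes and adjusted over the list alone. The nitrate reductase genes NIA1 and NIA2 had log2 fold changes of -0.40 ± 0.05 and -0.42 ± 0.06 (edgeR adjusted p = 0.00053 and 0.00127). The list's camera adjusted p was 5.69e-05, with an adjusted p = 0.238 under an estimated correlation. Of 27 abscisic acid, drought and cold genes 2 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.983), where COR15B rose (0.69 ± 0.07, edgeR adjusted p = 0.000132) and the cold regulator CBF2 fell (-1.03 ± 0.16, adjusted p = 0.0028). The number that rose was 1 without any 1 Col-0 library or without AtCXE15-OE replicate 2 or 3, and 4 without AtCXE15-OE replicate 1, while the number that fell was 1 without any 1 library other than AtCXE15-OE replicate 3. The clock list had 4 members that rose and 4 that fell of 18, and 8 and 7 adjusted over the list alone (camera adjusted p = 0.44), with PRR3 at 0.48 ± 0.07 and CCA1 at -0.36 ± 0.06. In it 2 rose without Col-0 replicate 1 or 2, and 2 fell without AtCXE15-OE replicate 3. No member of the photosynthesis list (20 genes) or the root list (17 genes) passed the edgeR test, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 edgeR gave 4 and 2 members, DESeq2 called 2 and 0, and limma-voom 0 and 0. Without AtCXE15-OE replicate 1 edgeR called 2 photosynthesis genes lower. Camera placed both lists lower (adjusted p = 0.000247 and 0.0373), which did not hold with an estimated correlation (adjusted p = 0.318 for both). The camera call of the root list was also lost without Col-0 replicate 2 (adjusted p = 0.332), AtCXE15-OE replicate 1 (0.0676) or AtCXE15-OE replicate 2 (0.152).

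In all, edgeR called 487 genes in AtCXE15-OE against Col-0, 163 higher and 324 lower, of which 53 changed at least 2-fold. Besides CXE15, CCD7 and CCD8, the highest log2 fold changes among called genes with a symbol and a mean of 1 CPM or more were those of RAP2.1 (2.69 ± 0.36), scpl30 (1.60 ± 0.29), the cellulase gene CEL3 (1.14 ± 0.17) and LTP4 (1.05 ± 0.22). The lowest were those of FAS4 (-6.45 ± 0.66), the cell wall invertase gene CWINV5 (-3.56 ± 0.42), BGLU47 (-2.26 ± 0.22), RRTF1 (-1.72 ± 0.25), PP2-A5 (-1.64 ± 0.30) and the abscisic acid hydroxylase gene CYP707A3 (-1.52 ± 0.17). FAS4 and CWINV5 were close to the floor in AtCXE15-OE (0.111 to 0.234 and 0.166 to 0.267 CPM), so that the size of their fold changes is uncertain. FAS4 and BGLU47 were not called when overlapping loci were summed (0.058 and -0.21, adjusted p = 0.702 and 0.145), and RRTF1 was then at -0.46. With limma-voom FAS4 and scpl30 were not called (adjusted p = 0.0648 for scpl30). The LTP4 call was lost without any 1 Col-0 library, without AtCXE15-OE replicate 2, without AtCXE15-OE replicate 3, and in 2 other alternatives (adjusted p up to 0.151). With library size as the only scaling the calls were 220 higher and 274 lower. The count fell to 308 without Col-0 replicate 1, 309 without Col-0 replicate 2 and 287 without AtCXE15-OE replicate 3, and DESeq2 called 840 genes.

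**Figure D2:**
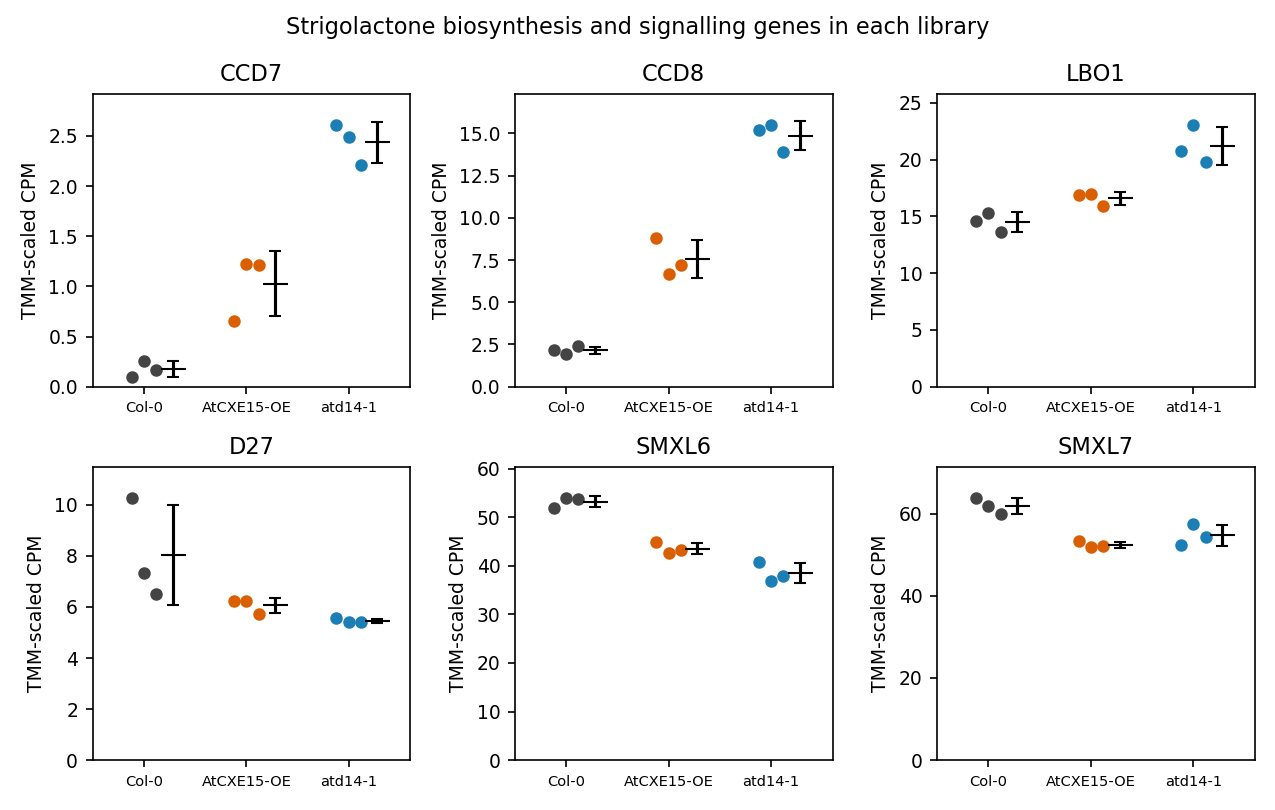
TMM-scaled CPM of 6 strigolactone genes in each library, with the mean and SD of 3 libraries at the right of each group. CCD7 and CCD8 are lowest in Col-0, at 0.173 and 2.15 CPM, and highest in atd14-1, at 2.44 and 14.9 CPM.

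The second comparison asked how the receptor mutant atd14-1 differs from Col-0. CCD7 rose to 2.44 ± 0.204 CPM and CCD8 to 14.9 ± 0.854 CPM (log2 fold changes 3.81 ± 0.39 and 2.79 ± 0.14, edgeR adjusted p = 2.16e-05 and 3.37e-08, the first against Col-0 values close to the floor), and LBO1, which acts late in the pathway, rose by a log2 fold change of 0.55 ± 0.09. With overlapping loci summed the group that holds CCD8 had a log2 fold change of 0.46 (edgeR adjusted p = 9.88e-05). D27 fell (-0.56 ± 0.16, edgeR adjusted p = 0.0328), a call lost without Col-0 replicate 1, without any 1 atd14-1 library or with library size as the only scaling (adjusted p up to 0.166). In the biosynthesis list 3 of 5 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.00549), with an adjusted p = 0.0849 under an estimated correlation. In the signalling list, which holds D14 itself, 2 of 14 members fell, D14 and SMXL6 (-0.47 ± 0.06), and 3 adjusted over the list alone, and its camera adjusted p of 0.0255 became an adjusted p = 0.0995 with an estimated correlation, 0.053 without Col-0 replicate 2 and 0.0766 without atd14-1 replicate 3.

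Photosynthesis genes were lower in atd14-1, where 16 of 20 measured members fell, over all genes and adjusted over the list alone. LHCA1, a light-harvesting gene, fell from 3383 ± 60.3 to 2002 ± 140 CPM (log2 fold change -0.76 ± 0.07, edgeR adjusted p = 9.19e-06), and LHCB2.1 had a log2 fold change of -0.83 ± 0.08. Counts of the LHCB and RBCS families can be shared between near-identical copies. The camera adjusted p was 5.37e-17, with an adjusted p = 0.0615 under an estimated correlation, while 0 of the 17 root genes passed the edgeR test, also adjusted over the list alone, 0 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 (median log2 fold change 0.06, camera adjusted p = 0.396). Phosphate starvation genes moved the other way, with 12 of 18 rising, over all genes and adjusted over the list alone. Among them SQD1, for sulfolipid synthesis, rose by a log2 fold change of 0.53 ± 0.05 (edgeR adjusted p = 6.39e-06), PHO1;H1 by 0.55 ± 0.08 and SPX1 by 0.49 ± 0.07. The camera adjusted p was 1.78e-10, with an adjusted p = 0.0615 under an estimated correlation.

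Touch and wounding genes fell in atd14-1 as well, 14 of 16 members and 15 adjusted over the list alone (camera adjusted p = 2.72e-21, adjusted p = 0.0458 with an estimated correlation). SZF1 was at -1.28 ± 0.06 and WRKY40 at -1.39 ± 0.11. Over the alternatives, summed overlapping loci included, WRKY40 was between -1.44 and -0.97. Of 27 abscisic acid, drought and cold genes 9 rose and 2 fell, and 13 and 4 adjusted over the list alone, where COR15B (1.65 ± 0.07), GolS2 (0.89 ± 0.09) and RD29A (0.90 ± 0.09) rose, and the cold regulators CBF1 and CBF2 fell (-1.12 ± 0.19 and -1.17 ± 0.16). The camera adjusted p of that list was 0.00216, with an adjusted p = 0.258 under an estimated correlation. Of 27 jasmonate genes 6 rose and 2 fell, also adjusted over the list alone, with LOX2 at 0.95 ± 0.07 and MYC2 at -0.35 ± 0.05 (camera adjusted p = 0.0938, fry adjusted p = 0.000659 for a rise on balance). Only 1 fell and 4 to 5 rose when any 1 of the 6 libraries was left out. In the nitrate list 4 of 8 members fell, also adjusted over the list alone, with NIA1 at -0.96 ± 0.05 (camera adjusted p = 0.000128, adjusted p = 0.0995 with an estimated correlation). In the clock list 5 of 18 members rose and 9 fell, and 6 and 9 adjusted over the list alone, with LNK2 at -0.99 ± 0.07, CCA1 at -0.75 ± 0.06 and GRP7 at 0.71 ± 0.07 (camera adjusted p = 0.0909, or 0.0359 with library size as the only scaling, and fry adjusted p = 0.00127 for a fall on balance). In the glucosinolate list 7 of 18 rose and 2 fell, and 8 and 3 adjusted over the list alone, with CYP79F1 at 0.54 ± 0.06 (camera adjusted p = 0.048, adjusted p = 0.303 with an estimated correlation). Its camera call was also lost without Col-0 replicate 3 (adjusted p = 0.141), without atd14-1 replicate 1 (0.0787), with a stricter filter (0.0546) and with RLE size factors (0.0501).

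In all, edgeR called 2556 genes in atd14-1, 1084 higher and 1472 lower, of which 206 changed at least 2-fold. With library size as the only scaling the split turned to 2241 higher and 968 lower, so the balance of directions rests on the composition factors. The highest log2 fold changes among called genes with a symbol and a mean of 1 CPM or more, besides CCD7 and CCD8, were those of MRD1 (7.65 ± 0.72), LTP4 (3.00 ± 0.23), RAP2.1 (2.94 ± 0.37) and HEI10 (2.88 ± 0.22). MRD1 and HEI10 belong to 4 loci that overlap in the table, so their counts are uncertain, and the sum of these loci was at 0.36. Besides D14, the lowest were those of CWINV5 (-2.80 ± 0.39), the sulfate assimilation gene APR2 (-2.28 ± 0.08), PP2-A5 (-2.23 ± 0.31), BGLU47 (-1.97 ± 0.22), CRK30 (-1.94 ± 0.18) and AIG1 (-1.89 ± 0.22). BGLU47 was at -0.30 with overlapping loci summed. The fold changes of MRD1 and CWINV5 are uncertain in size, since MRD1 was at 0 to 0.335 CPM in Col-0 and CWINV5 at 0.155 to 0.521 CPM in atd14-1. No excess of calls among genes near the 2 loci was detected in any of the 3 comparisons (40 tested neighbours of each, 2.5% to 10.0% called against 2.28% to 12.1% of other genes, Fisher's exact test, one-sided, adjusted p = 0.962 in all 6 tests).

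**Figure D3:**
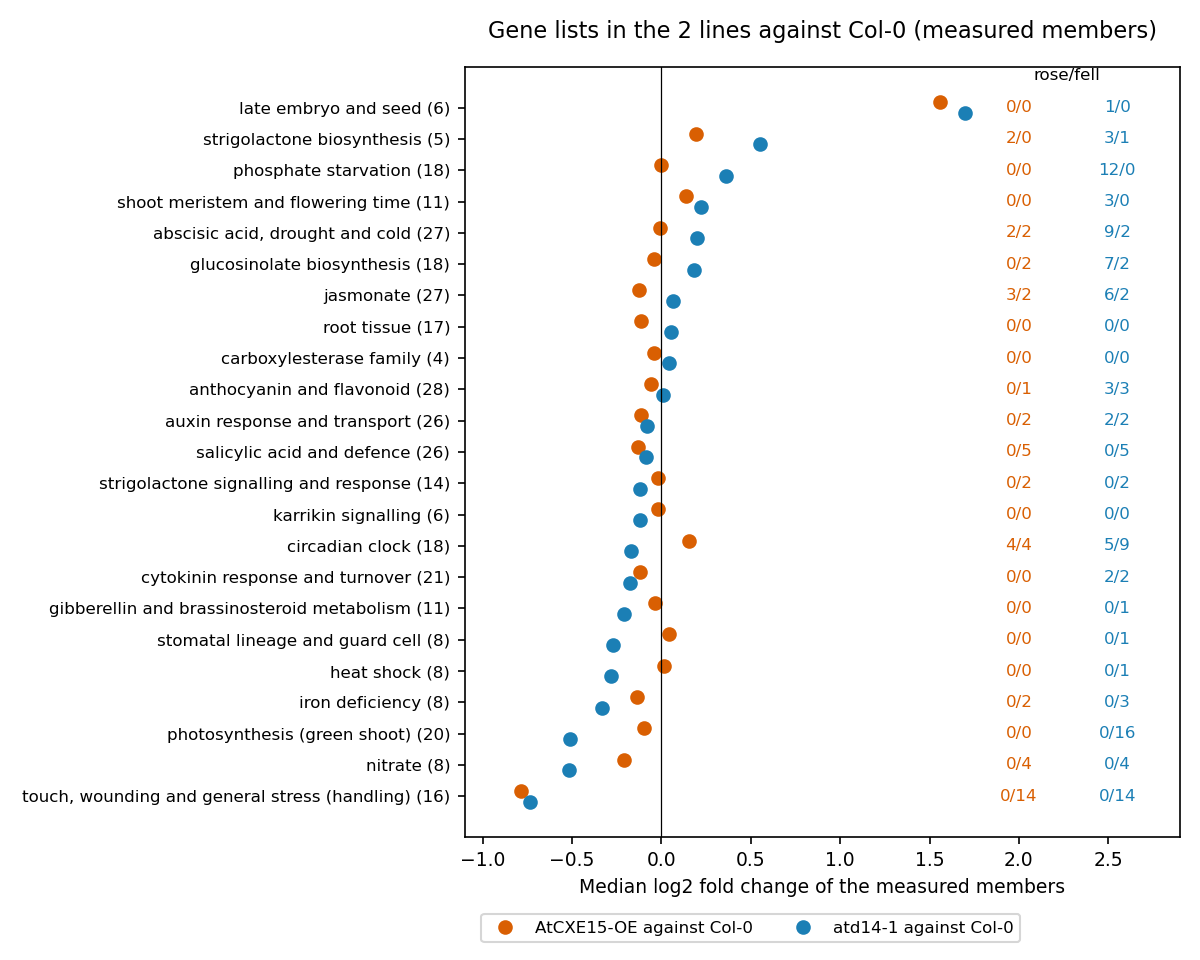
Median log2 fold change of the measured members of each of the 23 gene lists (number measured in parentheses) in AtCXE15-OE and atd14-1 against Col-0, with the numbers that rose and fell at the right. Touch and wounding genes are low in both lines (14 of 16 fell in each), while 16 of 20 photosynthesis genes fell and 12 of 18 phosphate starvation genes rose in atd14-1.

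The 2 lines were then compared over all genes. Of the 487 genes called in AtCXE15-OE, 373 were called in the same direction in atd14-1, 111 higher and 262 lower, against 8.25 and 22.3 for independent lists. In 40 simulations of unchanged groups at most 2 were shared, but these called at most 5 and 9 genes per comparison, so that value sets no limit on how far shared controls raise the overlap of real effects. The highest mean log2 fold changes among the shared genes were those of CCD7, RAP2.1, CCD8, scpl30 and LTP4. The lowest were those of CWINV5, BGLU47, PP2-A5, RRTF1 and WRKY40. Over the alternatives, summed overlapping loci included, RRTF1 in atd14-1 was between -1.75 and -0.34. The log2 fold changes correlated across genes with r = 0.499, but unchanged groups simulated against shared controls gave a mean r = 0.501, so the correlation itself was no higher than shared controls give. The simulations held no effects of the lines, so these values of r do not show where the observed correlation came from. Genes are not independent replicates. The covariance was 0.0918 against a simulated mean of 0.0597, a difference of 0.032, and a highest simulated value of 0.0714. Of the AtCXE15-OE calls 93.8% had the same sign in atd14-1, against 91.8% for as many top genes in the simulations. Those top genes held no effect and were ranked on deviations that the shared Col-0 libraries can carry. The 91.8% is therefore no baseline for genes with real effects. The 3 Col-0 libraries were not split between the lines, since 1 part would hold a single library, and part of the excess in shared calls may come from them. The shared count was 248 without Col-0 replicate 1, 239 without AtCXE15-OE replicate 3 and 571 with DESeq2.

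**Figure D4:**
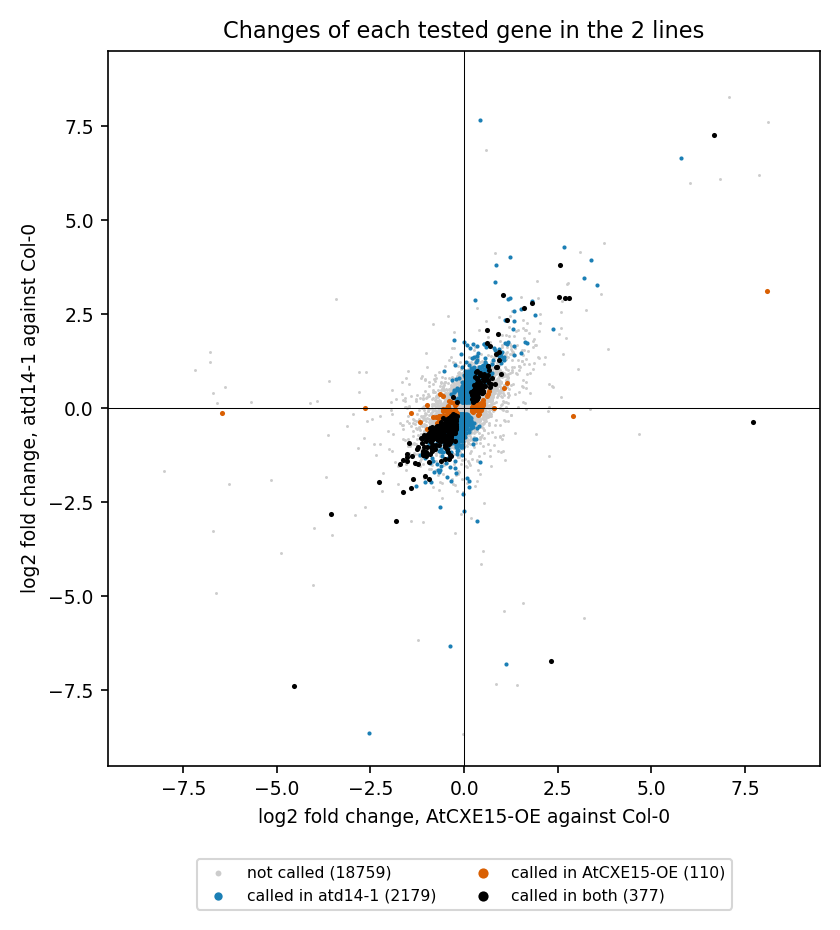
Log2 fold change against Col-0 of each of 21425 tested genes in AtCXE15-OE (horizontal axis) and atd14-1 (vertical axis), coloured by the edgeR call. Of the genes called in both lines 373 lie in the same direction and 4 in opposite directions.

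The direct comparison asked where AtCXE15-OE and atd14-1 differ. CCD8 was lower in AtCXE15-OE than in atd14-1 (log2 fold change -0.98 ± 0.13, edgeR adjusted p = 0.000533), and at -0.22 with overlapping loci summed. CCD7 was also lower (-1.24 ± 0.32, edgeR adjusted p = 0.0336), a call lost when any 1 of the 6 libraries compared was left out (adjusted p up to 0.111). Photosynthesis genes were higher in AtCXE15-OE, 14 of 20 over all genes and 16 adjusted over the list alone (camera adjusted p = 5.19e-15, adjusted p = 0.0629 with an estimated correlation). Phosphate starvation genes were lower, 10 of 18 and 14 adjusted over the list alone (camera adjusted p = 2.97e-12, adjusted p = 0.061 with an estimated correlation). In the touch list 1 of 16 members was lower in AtCXE15-OE, and 3 adjusted over the list alone (camera adjusted p = 0.184). It was 2 without AtCXE15-OE replicate 2 and 0 without atd14-1 replicate 2 or 3, and 1 was higher without atd14-1 replicate 2. Besides CXE15 and D14, the highest log2 fold changes among called genes with a symbol and a mean of 1 CPM or more were those of APR2 (2.24 ± 0.08), CRK30 (2.08 ± 0.18), SR30 (1.94 ± 0.11), SEN1 (1.51 ± 0.22) and BT2 (1.18 ± 0.09), and the lowest those of MRD1, FAS4, HEI10, SOT18 and LTP4. The SEN1 call was lost without atd14-1 replicate 1 or 2 (adjusted p up to 0.0544), and that of SOT18 without AtCXE15-OE replicate 2 or 3 or atd14-1 replicate 2 or 3 (adjusted p up to 0.0868). FAS4 was not called with limma-voom or with overlapping loci summed, where SR30 was at 0.41, MRD1 and HEI10 at -0.54 and SOT18 at -0.19. In all 1486 genes were called, 882 higher and 604 lower in AtCXE15-OE, or 551 higher and 1060 lower with library size as the only scaling. The count was 2232 without AtCXE15-OE replicate 1, 851 without AtCXE15-OE replicate 2, 777 without AtCXE15-OE replicate 3, 826 without atd14-1 replicate 1, 769 without atd14-1 replicate 2 and 924 without atd14-1 replicate 3.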

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

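The tests of the touch, clock and overlapping-locus patterns and of other splits were chosen after the results were seen, while the direct comparisons of the lines were planned. A total of 4 genes were called in opposite directions in the 2 lines against Col-0, and the direct edgeR comparison called each. CXE15 (AT5G06570) differed by a log2 fold change of 8.08, by construction of the line. Its call in atd14-1 against Col-0 was lost without any 1 Col-0 or atd14-1 library. AT2G16005 was lower in AtCXE15-OE and higher in atd14-1, with a log2 fold change of -0.60 between the lines. The sulfate transporter gene SULTR2;1 was also lower in AtCXE15-OE (log2 fold change -0.20, edgeR adjusted p = 0.0448) and higher in atd14-1 (0.18, edgeR adjusted p = 0.0256). It differed by -0.38 between the lines. Whether its calls against Col-0 hold with each library left out was not examined. The assembled locus newGene_781 was at 0.284 CPM in Col-0, 1.42 CPM in AtCXE15-OE and at 0 in every atd14-1 library. Direct tests between the lines passed for 11 lists by camera, with adjusted p = 0.00303 for strigolactone biosynthesis, 1.60e-05 for abscisic acid, drought and cold, 3.10e-05 for jasmonate, 0.0207 for gibberellin and brassinosteroid metabolism, 5.19e-15 for photosynthesis, 0.00791 for root tissue, 0.00583 for the stomatal lineage, 6.58e-05 for the circadian clock and for glucosinolate biosynthesis, 2.97e-12 for phosphate starvation and 0.0047 for nitrate. None of the 11 passed with an estimated correlation (the lowest adjusted p was 0.0539). Without AtCXE15-OE replicate 2 the defence and seed lists passed camera as well (adjusted p = 0.00183 and 0.0431).

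Touch and wounding genes were lower in both lines than in Col-0. A single Col-0 library is argued against, since at least 13 of the 16 members were called lower in each line with any 1 Col-0 library left out. A difference in how the Col-0 seedlings were handled or collected stays open, because handling was not recorded and would coincide with the groups. The lines hardly differed from each other in these genes (median log2 fold change -0.054), as either handling of Col-0 or a shared effect of reduced strigolactone signalling would give. The latter was not tested. Handling stays open in the same way for other genes lower in both lines, such as WRKY33 and WRKY46 of the defence list.

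In the clock list 4 genes rose and 4 fell in AtCXE15-OE, and 5 rose and 9 fell in atd14-1, without passing camera (adjusted p = 0.44 and 0.0909, the latter 0.0359 with library size as the only scaling). In AtCXE15-OE 2 rose without Col-0 replicate 1 or 2, and 2 fell without AtCXE15-OE replicate 3. The mean log2 CPM of 6 evening genes minus that of 7 morning genes, relative to Col-0, for genes chosen after their values were seen, was 0.57 ± 0.07 in AtCXE15-OE and 1.00 ± 0.01 in atd14-1 (SD, n = 3, Col-0 SD 0.113). Because of that choice the value does not test whether clock genes shifted as a group. Camera tests movement one way, so members that move oppositely cancel in it, and its result does not exclude a shift. Fry without regard to direction, on the list fixed beforehand, passed in AtCXE15-OE and atd14-1 (fry adjusted p = 1.14e-06 and 7.51e-07). It also passed for the cytokinin list in AtCXE15-OE (4.82e-06), where 0 members were called, so it is not particular to the clock. Collection of the lines at a later clock time than Col-0 stays open as an explanation of the members that changed. No collection time was given in the sources used here, so it cannot be told apart from an effect of the genotype. The same holds for other genes that differed between Col-0 and the lines, photosynthesis, nitrate and cold genes among them.

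Some of the largest differences were in genes that share a locus or sequence with others, of which FAS4 was at 0.172 CPM in AtCXE15-OE and 15.2 CPM in Col-0, and MRD1 at 0.127 CPM in Col-0 and 25.3 CPM in atd14-1. For FAS4 in AtCXE15-OE, the values are consistent with reads assigned to an overlapping locus, since the summed loci had a log2 fold change of 0.058 ± 0.052. For MRD1 in atd14-1 the summed loci rose by 0.36 ± 0.10 (edgeR adjusted p = 0.0347). A move of reads within these loci alone would leave the sum unchanged, so this rise argues against it as the whole explanation. Their other members hold most of the counts, so the sum does not give the share of MRD1 in the rise. For SOT18 between the lines the sum with its paralog SOT17 was -1.31 ± 0.50 (edgeR adjusted p = 0.209), too variable to decide. Background variation between the lines was not tested.

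For each comparison there are 10 splits of the 6 libraries, so that a share under 0.1 cannot be reached. The real split alone (1 of 10) gave 487 genes in AtCXE15-OE against Col-0, with 10 as the highest of the others. It gave 2556 in atd14-1 against Col-0, with 3 as the highest other, and 1486 between the lines, with 6 as the highest other.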

How the results depend on the processing

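Summing overlapping loci and counting list members with each library left out were chosen after the data had been seen, and the other alternatives before. DESeq2 called 840 genes in AtCXE15-OE against Col-0 and 571 shared genes, against 487 and 373. Requiring a 2-fold change left 53 genes in AtCXE15-OE against Col-0, 206 in atd14-1 against Col-0, 72 between the lines and 35 shared. An adjusted p under 0.01 left 220, 1360, 595 and 182. These follow from the stricter thresholds, while the cause for DESeq2 was not tested. With an estimated correlation 1 list passed camera in AtCXE15-OE, 1 in atd14-1 and 0 between the lines, against 8, 13 and 11 with the preset. In atd14-1 CXE15 was not called with limma-voom (-0.37, adjusted p = 0.548), with only the 6 libraries (-0.38, adjusted p = 0.166) or with the replicate block (-0.37, adjusted p = 0.0661), and the cause was not tested. With overlapping loci summed, 4 values changed sign and were no longer called: FAS4 (0.058) and WRKY53 (0.014) in AtCXE15-OE and CKX5 (-0.13) and WRKY53 (0.065) in atd14-1, which follows from the added counts of other genes. Leaving out each library gave 287 to 588 genes in AtCXE15-OE, 1711 to 1910 in atd14-1, 769 to 2232 between the lines, 239 to 388 shared genes, 5 to 8 lists past camera in AtCXE15-OE, 10 to 13 in atd14-1 and 11 to 13 between the lines, 0 to 5 called neighbours of either locus, correlations of 0.423 to 0.615 and log2 fold changes of CXE15 in atd14-1 of -0.41 to -0.34. Fewer libraries lower the power, but without AtCXE15-OE replicate 1 the counts rose, and the cause was not tested. Of 152 called values of named genes, 108 kept their call and direction under every alternative run on them. Replicate numbers did not pair the libraries (correlations of same-numbered libraries from -0.05 to 0.04), and the replicate block gave 461, 2576 and 1561 genes, 353 shared, and 6, 12 and 11 lists past camera. Under the block the lists for strigolactone biosynthesis (adjusted p = 0.0567) and seed (0.0567) in AtCXE15-OE and glucosinolates (0.0512) in atd14-1 no longer passed, and SMXL7 in AtCXE15-OE was not called (-0.24, adjusted p = 0.0567). CRA1 in atd14-1 (edgeR adjusted p = 0.069), the 1 seed gene called there, and SOT18 between the lines were also not called under it. By fry without the block 6, 17 and 14 lists passed. With the block, fry was no longer passed by the signalling and defence lists in AtCXE15-OE (fry adjusted p = 0.0873 for both). Nor was it passed by the heat shock and seed lists in atd14-1 (0.0614 and 0.0681) or the heat shock list between the lines (0.127). In counts simulated at these depths and replicate numbers, 42.4% of 1.5-fold changes in AtCXE15-OE and 43.3% in atd14-1 were recovered, so many changes of that size would be missed.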

Other observations

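In the iron list 2 of 8 members fell in AtCXE15-OE and 3 in atd14-1, also adjusted over the list alone, with the nicotianamine synthase gene NAS4 at -0.58 and -0.54 (camera adjusted p = 0.0188 and 0.00264, and adjusted p = 0.238 and 0.0728 with an estimated correlation). In AtCXE15-OE 1 iron gene fell without Col-0 replicate 2 or 3 or AtCXE15-OE replicate 2 or 3, and the camera call was lost without AtCXE15-OE replicate 1 (adjusted p = 0.0586) and with no filter (0.216). In the meristem and flowering list 3 of 11 rose in atd14-1, also adjusted over the list alone, with FUL at 1.14 ± 0.21 and KNAT1 at 0.54 ± 0.10 (camera adjusted p = 0.0246, adjusted p = 0.15 with an estimated correlation, 0.0984 without Col-0 replicate 3 and 0.0533 with library size as the only scaling). FLC also rose in atd14-1 (log2 fold changes of 0.53 to 0.68 over the alternatives). Its call was lost without Col-0 replicate 1 or 2 or atd14-1 replicate 1 or 2 (edgeR adjusted p up to 0.0865). In AtCXE15-OE 0 were called in that list, with 2 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom. In the seed list 1 of 6 rose in atd14-1, and 2 adjusted over the list alone, where the storage protein gene CRA1 rose by 2.48 ± 0.46 (camera adjusted p = 0.00879, adjusted p = 0.247 with an estimated correlation), and 2 rose without Col-0 replicate 1. In AtCXE15-OE 0 of the seed genes were called and 1 adjusted over the list alone, with 2 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom (camera adjusted p = 0.0252, adjusted p = 0.318 with an estimated correlation). Without Col-0 replicate 2, 1 was called. The camera call was lost without Col-0 replicate 2 (adjusted p = 0.114), without AtCXE15-OE replicate 2 (0.0748) and with library size as the only scaling (0.0566).

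In atd14-1, 5 of 26 defence genes fell (camera adjusted p = 0.127), and 2 rose and 8 fell adjusted over the list alone. WRKY53, one of the 5, was at 0.065 with overlapping loci summed, and 1 gene rose without atd14-1 replicate 2. The cytokinin list had 2 of 21 that rose and 2 that fell there (3 and 3 adjusted over the list alone, camera adjusted p = 0.396), the auxin list 2 of 26 each way (2 and 2, camera adjusted p = 0.358) and the anthocyanin list 3 of 28 each way (3 and 3, camera adjusted p = 0.921). A single member fell in the gibberellin and brassinosteroid list (1 adjusted over the list alone, camera adjusted p = 0.0129), the stomatal list (3, camera adjusted p = 0.0192) and the heat shock list (2, camera adjusted p = 0.213), and the first 2 had an adjusted p = 0.0995 with an estimated correlation. Several of these counts rest on single libraries. In the cytokinin list 0 rose without Col-0 replicate 1 or atd14-1 replicate 2 and 1 without Col-0 replicate 2, and 1 fell without Col-0 replicate 1 or 3 or atd14-1 replicate 1 or 2. CKX5, one of the 2 that rose, was at -0.13 with overlapping loci summed. In the anthocyanin list F3H and PAP1 were among those that rose, and LBD39 and MYBL2 among those that fell. Camera tests movement one way, so such opposite moves cancel in it. In that list 0 rose without Col-0 replicate 3 or atd14-1 replicate 3, and 1 without any 1 of the other libraries. In the auxin list 1 rose without Col-0 replicate 3. The gibberellin and brassinosteroid list had 0 without Col-0 replicate 1 or atd14-1 replicate 1 or 3, and the heat shock list 2 without Col-0 replicate 3. The camera call of the stomatal list was lost without Col-0 replicate 3 (adjusted p = 0.0651). In AtCXE15-OE, 2 auxin genes fell (3 adjusted over the list alone, camera adjusted p = 0.152), and 1 anthocyanin gene (1) and 2 glucosinolate genes fell (3 rose and 6 fell adjusted over the list alone), while 3 jasmonate genes rose and 2 fell (3 and 5), each of these 3 lists with a camera adjusted p of 0.209. The anthocyanin gene that fell in AtCXE15-OE was LBD39, which is also in the nitrate list. There 1 auxin gene fell without Col-0 replicate 3. In the glucosinolate list 1 fell without Col-0 replicate 1 or AtCXE15-OE replicate 1 or 2, 0 without Col-0 replicate 2 or AtCXE15-OE replicate 3, and 2 rose without AtCXE15-OE replicate 1. In the jasmonate list 1 rose without Col-0 replicate 2 or 3, and 1 fell without Col-0 replicate 1 or 2 or AtCXE15-OE replicate 2 or 3.

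By edgeR, 0 members were called in AtCXE15-OE in the phosphate (1 at an unadjusted p under 0.05, 1 by DESeq2), cytokinin (6 and 0), gibberellin and brassinosteroid (1 and 0), stomatal (1 and 1) and heat shock lists (0 and 0), with 0 by limma-voom in each. Adjusted over the list alone, 1 phosphate gene and 1 stomatal gene were called there, and without AtCXE15-OE replicate 1, 1 phosphate gene was called over all genes. The camera adjusted p-values were 0.844, 0.235, 0.697, 0.983 and 0.87. The karrikin (6 genes) and carboxylesterase (4 genes) lists, from which DLK2 and CXE15 were left out for lack of a symbol in the annotation, had 0 called by edgeR, DESeq2 or limma-voom in either line, also adjusted over the list alone, and at an unadjusted p under 0.05 each had 0 in AtCXE15-OE and 1 in atd14-1 (camera adjusted p = 0.66 and 0.87 in AtCXE15-OE, 0.222 and 0.461 in atd14-1). CXE15 itself was called in both lines (7.70 and -0.37), the call in atd14-1 being lost without any 1 Col-0 or atd14-1 library.

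Fry and camera at the preset correlation answer different questions and parted on 13 of the 69 tests. In AtCXE15-OE the photosynthesis, root and seed lists passed camera and not fry (fry adjusted p = 0.104, 0.176 and 0.124), and the signalling list passed fry alone. In atd14-1 the karrikin (fry adjusted p = 0.0254, lower), heat shock (0.0403, lower), jasmonate and clock lists passed fry alone. Between the lines fry alone was passed by the signalling list, which holds D14 (fry adjusted p = 0.000324, higher in AtCXE15-OE), and by the iron (0.000733, higher), meristem (0.0289, lower) and heat shock lists (0.0489, higher), while the root list passed camera alone (fry adjusted p = 0.0538).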
